A study of Mus musculus with 9 samples.

How the data were processed

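Liver RNA was sequenced from 9 NSG mouse samples, 3 after injections of phosphate-buffered saline (PBS) into the tail vein, 3 after extracellular vesicles (EVs) of MCF-10A cells and 3 after EVs of MDA-MB-231 cells, each given for 5 weeks. Libraries were made with the TruSeq RNA kit from 1 µg of total RNA, per the labels' protocols; whether the kit kept strand information is not given in the sources used here. The deposited table holds TPM for each library, a unit of transcript abundance already divided by transcript length and by the library total. HISAT2, StringTie and RSEM are named in the submitters' processing notes with the mouse build GRCm39, without versions or order of use. The TPM values of the authors were used as deposited. They keep no read depth, so the depth of each library is unknown and no counting interval can be given.

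The table lists 61473 features, 55414 with Ensembl identifiers and 6059 loci assembled from the reads. Of the Ensembl features, 1401 carry no symbol, and 79 symbols stand on more than 1 feature. TPM of the PBS and MDA-MB-231 EV libraries summed to between 999999.5 and 1000000.5. The MCF-10A EV libraries summed to 979351, 946777 and 934986, and every assembled locus is at 0 in them. Assembled loci held between 1.21% and 5.70% of the TPM of the other 6 libraries. They were left out of the comparisons after this was seen, a change from the plan, and tested only within those 6 libraries as an added alternative. No library was removed or rescaled for the values reported first.

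Values were tested as log2(TPM + 1) with limma 3.58.1 in R 4.3.3, with a mean per group over all 9 libraries, a trended prior variance and two-sided tests. Genes with a mean of at least 1 TPM were kept, 12860 in all. The Benjamini-Hochberg adjustment was applied per comparison, and a gene was called at an adjusted p under 0.05. Fold changes are on the log2(TPM + 1) scale, which understates the change of low genes. Only values listed above 0 in both groups have a fold; for a gene listed at 0 throughout a group the TPM of each library is given. The labels number the samples within a group but do not say that each came from a separate mouse, so the p-values measure only the spread between these samples.

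Gene lists were tested with limma's camera at its preset correlation of 0.01 between genes, adjusted over all lists with at least 5 tested genes; camera compares the genes of a list with all other tested genes. The same lists were tested with a correlation estimated from the data and with limma's fry, and members were also adjusted over the list alone. Counts of list genes above or below 0 stand beside a shift of all tested genes. Of these, 69.74% were above 0 in MDA-MB-231 EV against PBS. The share was 65.05% in MDA-MB-231 EV against MCF-10A EV and 56.78% in MCF-10A EV against PBS. The 36 lists cover sterol and lipid metabolism (cholesterol synthesis and uptake, SREBP processing, fatty acid and triglyceride synthesis, bile acids, cholesterol export and LXR targets, fatty acid oxidation and PPARA targets), gluconeogenesis and glycolysis, the circadian clock, immediate early genes, the glucocorticoid response, acute phase proteins, interferon and NF-kB responses, the unfolded protein response, heat shock, xenobiotic metabolism, NRF2 targets, the cell cycle and extracellular matrix. They also cover pericentral and periportal, male-biased and female-biased liver genes, secreted hepatocyte proteins, markers of Kupffer cells, monocytes and dendritic cells, neutrophils, lymphocytes, sinusoidal endothelium, stellate cells, cholangiocytes, erythroid cells and of pancreas, fat and mesothelium, and mitochondrially encoded, nuclear oxidative phosphorylation and ribosomal protein genes. The lymphocyte list had 3 tested genes, too few, and was not tested, which leaves 35.

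Sites for miR-9-5p were searched in the longest annotated 3' UTR of each gene, of 50 nt or more, in GENCODE M21 (GRCm38), matched by Ensembl identifier; 52081 of the 55414 identifiers are in that annotation, whose build differs from that of the authors. A 3' UTR was found for 11148 tested genes (86.7%). The mean log2 change of genes with the 8-mer ACCAAAGA was set against that of the other genes after regression on UTR length, GC fraction and mean expression. Its distance from the median of 168 words with the same bases, the site included, gives a permutation p over words.

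The genes named follow a fixed rule. In each comparison they are the 10 higher and 10 lower called genes with the largest change whose groups do not overlap and whose higher group has a mean of at least 5 TPM, without predicted genes. In addition a fixed set of sterol genes is always named, with up to 4 members with the smallest p of each list described and, where no gene was called, the 10 genes with the smallest p. Some genes that the rule names are not reported here. A few other genes are named beside them and are said to have been chosen after their values were seen. The groups, tests, lists, naming rule and most alternatives were fixed before the data were examined. Those alternatives were median-ratio scaling, quantile normalization, removal of the 10 most abundant genes, a pseudocount of 0.1, no filter, a filter at a mean of 5 TPM, only the libraries of the groups compared, robust moderation, array weights, the replicate number as a block, each library left out in turn, and a 7-mer site or all 3' UTRs of a gene. The replicate numbers come from the sample titles. They were read as pairing the samples of 2 groups where every same-numbered pair correlated above 0.1 in its deviations from the group means. This held between the vesicle groups (0.336, 0.11 and 0.436; other pairs -0.337 to 0.116) and not for the other comparisons; the labels give no shared animal, litter or day. The count-based tool among the alternatives was not run because the table holds no counts. Chosen after seeing the data were the fit without the 2 libraries that stand apart, the fit on features shared by both sets of libraries, and the test of the assembled loci. The fit on shared features also rescaled each library to the same total.

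The steps were tested on simulated data before use, with 200 genes changed among the 12860. For MDA-MB-231 EV against PBS, 0% of genes with a simulated log2 change of 1 were recovered, 48% at 2, 68% at 3 and 96% at 5. For MDA-MB-231 EV against MCF-10A EV the shares were 2%, 26%, 60% and 86%, and for MCF-10A EV against PBS 0%, 40%, 72% and 86%. Unchanged genes called numbered 3, 6 and 2. A list shifted by 1 was called in each simulation and none of the 34 unshifted lists was, and a planted site shift of -0.20 came back as -0.20, -0.22 and -0.21. Simulated genes varied independently of each other, whereas the median correlation estimated within the real lists was 0.354. The simulation therefore cannot show how often unshifted lists are called in the real libraries. Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9 was used for reading and drawing.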

Results

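Liver transcriptomes were measured in 9 libraries of NSG mice, an immunodeficient strain. Of these, 3 followed PBS injections, 3 followed EVs of MCF-10A, a non-tumorigenic human breast epithelial line, and 3 followed EVs of MDA-MB-231, a human triple-negative breast cancer line, given by tail vein for 5 weeks. The series title places the question in the cholesterol balance of the host and in miR-9-5p secreted by cancer cells. Between 17403 and 20070 Ensembl features were above 0 TPM per library. PBS 1 and MDA-MB-231 EV 3 stood apart from the rest of their groups: Xist, the long RNA of the inactive X chromosome, was at 320 and 273 TPM there and between 7.11 and 74.9 TPM in the other 7. Mug2, a secreted protease inhibitor, was at 750 and 789 TPM against at most 32.1 TPM. MDA-MB-231 EV 2 differed from its group the other way, with the lowest Xist, at 7.11 TPM against at least 36.8 TPM elsewhere. The nuclear RNA Malat1 was at 5.66 TPM in that library and at least 25.2 TPM in every other. The same library had the fewest Ensembl features above 0, 17403. MCF-10A EV 1 held 28585 TPM of Saa1, an acute phase apolipoprotein, where the other two of its group held 232 and 1211 TPM. These genes, and those of single libraries named later, were chosen after their values were seen. Mitochondrially encoded genes with a symbol made up 26.3%, 12.1% and 8.10% of TPM in PBS 1 to 3. The shares were 5.63%, 7.31% and 9.36% in the MCF-10A EV libraries and 6.50%, 4.96% and 11.7% in the MDA-MB-231 EV libraries.

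The comparison of MDA-MB-231 EV with PBS asks what the cancer vesicles did to liver genes, those of sterol control among them. Scap, which escorts the SREBP transcription factors to the Golgi, was at 28.1 ± 5.88 TPM (SD, n = 3) after MDA-MB-231 EVs and 15.8 ± 2.60 TPM after PBS, with no overlap between the groups. Insig2, which holds Scap in the endoplasmic reticulum, was at 83.6 ± 24.0 and 44.1 ± 21.5 TPM. Their log2 changes of 0.78 ± 0.36 (SE) and 1.01 ± 0.50 missed the threshold, with a limma adjusted p of 1 for both. Insig1, the paralog of Insig2, was at 90.7 ± 85.2 and 60.3 ± 24.2 TPM, a log2 change of 0.19 ± 0.67. MDA-MB-231 EV 1 held 187 TPM of it and the other two of that group 25.0 and 60.2 TPM. Hmgcs1, which makes HMG-CoA for the mevalonate pathway, was at 124 ± 86.7 and 254 ± 168 TPM (log2 change -0.98 ± 0.65). The log2 changes were 0.15 ± 0.62 for Srebf1 and 0.20 ± 0.39 for Srebf2, the genes of both SREBP factors. Sqle, which makes squalene epoxide, gave 0.18 ± 0.55. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, gave -0.05 ± 0.66 and the cholesterol exporter Abca1 0.23 ± 0.53. None of these 9 genes passed, and all had a limma adjusted p of 1 beside a median change over all tested genes of 0.21.

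**Figure D1:**
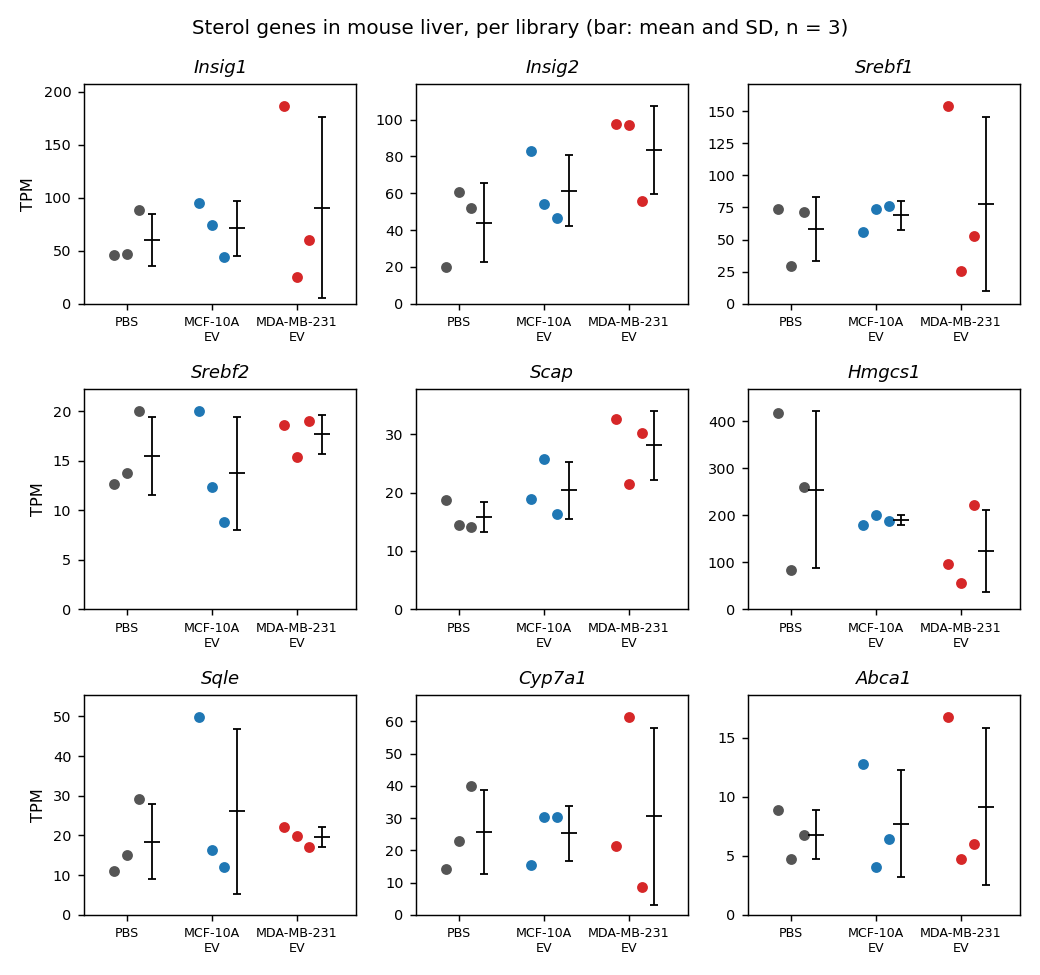
TPM of 9 sterol genes in mouse liver, on a linear axis from 0, by group (PBS, MCF-10A EV, MDA-MB-231 EV); points are libraries and the black bar beside them is the mean with its SD (n = 3). Scap is the gene whose MDA-MB-231 EV points all lie above its PBS points, at 28.1 against 15.8 TPM on average.

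No gene passed the limma threshold in MDA-MB-231 EV against PBS: 0 of 12860 at an adjusted p under 0.05, with 199 at an unadjusted p under 0.05 where 643 are expected by chance. That number of 199 depends on the libraries. Over leave-outs it ran from 96 without MDA-MB-231 EV 1 to 937 without MDA-MB-231 EV 3, and with array weights it was 853. The groups did not overlap for 776 genes (6.03%), where chance gives 10%. The smallest p belonged to Apba2, a neuronal adaptor protein, at 0.707 ± 0.0945 TPM after MDA-MB-231 EVs and 9.91 ± 7.41 TPM after PBS (log2 change -2.46 ± 0.50). Osgin1, an oxidative stress response gene, was at 75.5 ± 19.6 against 27.7 ± 5.39 TPM (1.40 ± 0.36). It was the 1 list member past the threshold when adjusted over the list alone (NRF2 targets, limma adjusted p = 0.0370), against 0 over all genes. Gucy2c, an intestinal guanylate cyclase receptor, was at 8.42 ± 2.89 against 30.8 ± 11.2 TPM (-1.72 ± 0.45). The axonemal dynein gene Dnai1 was at 3.16 ± 1.94 against 15.2 ± 6.33 TPM (-2.02 ± 0.51), and Usp9y at 0.343 ± 0.595 against 6.46 ± 0.841 TPM (-2.55 ± 0.56). Ddx3y, Eif2s3y, Kdm5d and Uty, other genes of the Y chromosome looked up after this was seen, were at most at 0.13 TPM in any library, so the Usp9y value cannot be read as Y chromosome expression. Capn11, a calpain protease gene, gave 2.26 ± 0.53. The remaining 4 of the 10 smallest p values were Zfp862-ps (-1.86 ± 0.45), Gm32872 (-1.85 ± 0.49), Marcksl1-ps4 (2.19 ± 0.59) and Snora73b, listed at 0 in all MDA-MB-231 EV libraries and at 2.40, 11.2 and 1.86 TPM in PBS 1 to 3. Without PBS 1 the count became 24, of which 23 were listed at 0 in all but PBS 2 and PBS 3, such as the 5S rRNA gene n-R5s144 (847 and 477 TPM there). Without MDA-MB-231 EV 3 it became 5, and without both libraries 28, a choice made after seeing the data.

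By group, the mitochondrially encoded genes fell most in MDA-MB-231 EV against PBS: 12 of 13 were below 0, with a median log2 change of -1.15, or -1.36 relative to the median of all genes (camera adjusted p = 4.8e-12; with an estimated correlation the adjusted p was 0.721). The cytochrome b gene mt-Cytb gave -1.18 ± 0.51, mt-Nd6 -1.36 ± 0.52, and the cytochrome oxidase genes mt-Co3 and mt-Co1 -1.78 ± 0.81 and -1.15 ± 0.53. It was the 1 list of the 13 called that stayed called whichever single library was left out, with camera adjusted p between 2.9e-17 and 1.2e-05. PBS 1, with its 26.3% mitochondrial share, sets much of the size: without it the median was -0.65. Genes of metabolism and of Kupffer cells, the resident macrophages of the liver, rose relative to the other genes at the preset correlation. With an estimated correlation none was called, with an adjusted p of 0.870 for fatty acid oxidation and 0.721 for the other 5. The medians were 0.55 for fatty acid oxidation and PPARA targets (27 of 30 above 0, camera adjusted p = 0.0222, with the thioesterase gene Acot3 at 2.11 ± 0.88) and 0.57 for xenobiotic metabolism (21 of 24, 0.0306), with Por, the electron donor of cytochromes P450, at 1.16 ± 0.44 and Ugt1a1 at 1.85 ± 0.76. They were 0.72 for NRF2 targets (12 of 13, 0.0222) and 0.55 for gluconeogenesis and glycolysis (18 of 23, 0.0378; Got1 1.09 ± 0.49, Pklr 1.11 ± 0.55). They were 0.65 for Kupffer cell markers (17 of 18, 0.0220; Folr2 0.89 ± 0.50, Timd4 0.78 ± 0.45, Cd5l 1.36 ± 0.94) and 0.45 for ribosomal proteins (26 of 27, 0.00257; Rpl3 1.21 ± 0.56).

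The other 6 lists called in MDA-MB-231 EV against PBS fell relative to the other genes at the preset correlation, and each had an adjusted p of 0.721 with an estimated correlation. Camera adjusted p was 0.00945 for male-biased liver genes (median -0.31, 11 of 16 below 0, Nudt7 at -0.72 ± 0.50) and for interferon response (-0.08, 19 of 26). Among interferon genes Isg15 gave -0.66 ± 0.50, Ifit1 -0.61 ± 0.48 and Irf7 0.49 ± 0.36. Camera adjusted p was 0.0220 for heat shock proteins, 0.0316 for cholangiocyte markers (-0.14, 7 of 10; Krt19 -0.80 ± 0.54) and 0.0356 both for extracellular matrix and for markers of pancreas, fat and mesothelium (-0.50, 4 of 6). The heat shock median was 0.03 and the mean -0.20, and the matrix median was 0.04 and the mean -0.06, so median and test differ in sign there. Fat genes in PBS 2 stood behind the last list: Cfd, the adipocyte factor D, was at 285 TPM in that library against at most 5.30 TPM in the others, and Adipoq at 17.6 against at most 0.970 TPM.

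Most of these list calls were lost when some single library was left out, in part with a median near that of all libraries; medians are given here with camera adjusted p. Without PBS 1 they were 0.28 for fatty acid oxidation (0.962), 0.52 for gluconeogenesis (0.205), 0.53 for xenobiotic metabolism (0.377), 0.36 for NRF2 targets (0.617) and 0.37 for Kupffer markers (0.771). Ribosomal proteins turned down by camera's direction (0.11, 0.699). Without PBS 2 they were 0.05 for heat shock (0.457), 0.41 for matrix (0.956), which turned up, and 0.21 for male-biased genes (0.131). The same fit gave -0.15 for cholangiocyte markers (0.244) and 0.32 for pancreas and fat markers (0.870). Without PBS 3 they were 0.42 for oxidation (0.0557), 0.43 for gluconeogenesis (0.0784) and -0.22 for male-biased genes (0.153). Without MDA-MB-231 EV 1 they were 0.12 for oxidation (0.838), 0.33 for xenobiotic metabolism (0.155) and 0.30 for NRF2 targets (0.286). In that fit Kupffer markers had 0.51 (0.0579), cholangiocyte -0.25 (0.0937) and fat markers -0.09 (0.771). Without MDA-MB-231 EV 2 they were 0.41 for oxidation (0.786), 0.63 for gluconeogenesis (0.124), 0.77 for xenobiotic metabolism (0.295) and 0.58 for NRF2 targets (0.409). There matrix had 0.05 (0.0620), Kupffer 0.39 (0.710), cholangiocyte 0.08 and fat markers -0.29 (both 0.0712) and ribosomal proteins 0.40 (0.630). Without MDA-MB-231 EV 3 they were 0.30 for gluconeogenesis (0.259), 0.05 for interferon (0.640), and 0.36 for heat shock (0.617) and 0.35 for male-biased genes (0.787), both of which turned up. This fit also gave -0.02 for matrix (0.623), -0.31 for cholangiocyte (0.205) and -0.79 for fat markers (0.190). Leaving out MCF-10A EV 1, 2 or 3, which enter through the shared spread and the filter, gave -0.24 (0.0846), -0.24 (0.0710) and -0.32 (0.0803) for the fat markers, and 0.55 (0.0512) for gluconeogenesis without MCF-10A EV 3. Calls that were kept moved in size by over 1.5 times in some leave-outs. Medians were 0.83 and 0.95 for oxidation without PBS 2 and MDA-MB-231 EV 3, 1.09 for NRF2 targets without MDA-MB-231 EV 3 and 0.75 for ribosomal proteins without PBS 2. They were -0.22, -0.40 and 0.06 for interferon without PBS 3, MDA-MB-231 EV 1 and MDA-MB-231 EV 2, and -0.60 for male-biased genes without MDA-MB-231 EV 2. Without PBS 3 they were -0.37 for cholangiocyte and -0.09 for fat markers. The heat shock median went from -0.41 without MDA-MB-231 EV 2 to -0.08 without MDA-MB-231 EV 1, and that of matrix from -0.37 without MDA-MB-231 EV 1 to -0.03 without PBS 3. Quantile normalization left 4 lists called, and so did array weights.

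In MDA-MB-231 EV against PBS most genes of the sterol lists were above 0, and so were 69.74% of all tested genes. None of these lists was called. Of 23 genes of cholesterol synthesis and uptake, 20 were above 0 and 16 above the median of all genes. The median of the list was 0.33, or 0.13 above that of all genes (camera adjusted p = 0.172). Pmvk and Fdft1, enzymes of the mevalonate and squalene steps, gave 1.05 ± 0.48 and 1.16 ± 0.59. SREBP processing and sterol sensing had 13 of 14 genes above 0, 8 above the median of all genes, and a median of 0.30 (0.0843). Cholesterol export and LXR targets had 20 of 23 above 0, 16 above the median of all genes, and a median of 0.40 (0.0610). There Lcat, which esterifies plasma cholesterol, was at 0.71 ± 0.36. Bile acid genes had a median of 0.36 (0.369; Abcb4, the phospholipid exporter of bile, 1.26 ± 0.53) and fatty acid and triglyceride synthesis 0.39 (0.266; Tkfc 0.85 ± 0.36). These results turned on the libraries kept. Without PBS 3 medians were 0.63 for cholesterol synthesis (camera adjusted p = 3.8e-04), 0.51 for SREBP processing (0.0144) and 0.27 for LXR targets (0.0260). Without MDA-MB-231 EV 3 they were 0.48 (0.0301), 0.63 (0.0194) and 0.44 (0.0290), upward in each case. With PBS 1 and MDA-MB-231 EV 3 both left out, a choice made after seeing the data, they were 0.32 (0.232), 0.60 (0.0309) and 0.54 (0.0363). Over all leave-outs cholesterol synthesis ranged from 3.8e-04 to 0.893 and SREBP processing from 0.0144 to 0.960. Estimating the correlation gave adjusted p of 0.921 for cholesterol synthesis and 0.721 for SREBP processing and LXR targets.

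**Figure D2:**
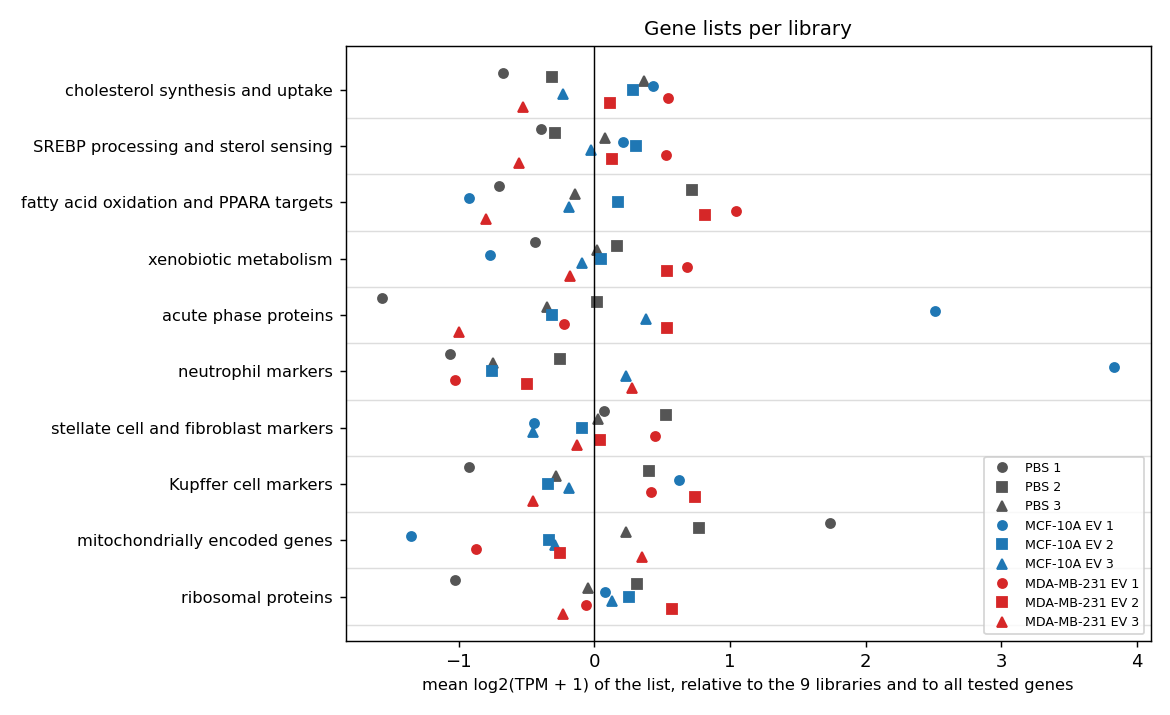
Mean log2(TPM + 1) of 10 gene lists per library (horizontal axis, log2 units relative to the 9 libraries and to all tested genes); each point is a library, with PBS in grey, MCF-10A EV in blue and MDA-MB-231 EV in red, and the symbol gives the replicate. MCF-10A EV 1 lies at 3.83 for neutrophil markers and 2.51 for acute phase proteins.

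The remaining lists of MDA-MB-231 EV against PBS were not called. Median log2 changes were 0.64 for acute phase proteins (camera adjusted p = 0.289), 0.46 for NF-kB cytokines (0.296), and 0.42 for immediate early genes (0.213). They were 0.31 for the unfolded protein response (0.549), 0.37 for the glucocorticoid response (0.787), 0.21 for the circadian clock (0.638) and 0.31 for the cell cycle (0.563). They were 0.52 for periportal genes (0.0843), -0.02 for pericentral genes (0.375), and 0.51 for female-biased genes (0.0902). The median was 0.23 for secreted hepatocyte proteins (0.638) and 0.23 for nuclear oxidative phosphorylation genes (0.462). Cell type markers gave 0.01 for monocytes and dendritic cells (0.207), 0.49 for neutrophils (0.926), 0.22 for sinusoidal endothelium (0.926), 0.24 for stellate cells (0.563) and 0.27 for erythroid cells (0.991). The camera direction was downward, against a median or mean above 0, for the pericentral, monocyte and stellate lists. Of all 22 lists not called, 12 were called in at least 1 fit that left out a library, in both directions. Nuclear oxidative phosphorylation genes went down without PBS 1 (0.00287) and up without PBS 2 (0.0117), PBS 3 (0.0315) or MDA-MB-231 EV 3 (0.0194).

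No shift apart from the other genes was found for those with an 8-mer site for miR-9-5p. The 494 of 11148 genes with ACCAAAGA in the longest 3' UTR differed by -0.015 ± 0.018 log2 units (SE; 95% interval -0.050 to 0.019) from genes without it in MDA-MB-231 EV against PBS. The permutation p over 168 words was 0.744. In MDA-MB-231 EV against MCF-10A EV the difference was -0.008 ± 0.023 (-0.052 to 0.037, permutation p = 0.690), and in MCF-10A EV against PBS -0.008 ± 0.023 (-0.052 to 0.038, permutation p = 0.518). These SEs and intervals are taken over genes as if independent and leave out the spread between samples. They therefore set no bound on an effect of the vesicles. Leaving out a library turned the sign in each comparison, up to 0.006 without MDA-MB-231 EV 2, 0.018 without MCF-10A EV 3 and 0.023 without MCF-10A EV 1 in that order. Insig1, on chromosome 5 (28071363 to 28078662, plus strand, GRCm38), holds no 8-mer site. Its 3' UTR of 1845 nt holds the 7-mer ACCAAAG at 28078507 to 28078513. Insig2, on chromosome 1 (121304353 to 121332589, minus strand), and Scap, on chromosome 9 (110333288 to 110384950, plus strand), hold neither in 3' UTRs of 1556 and 152 nt. Cyp7a1, on chromosome 4 (6265612 to 6275633, minus strand), holds the 7-mer at 6266195 to 6266201 in its 3' UTR.

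**Figure D3:**
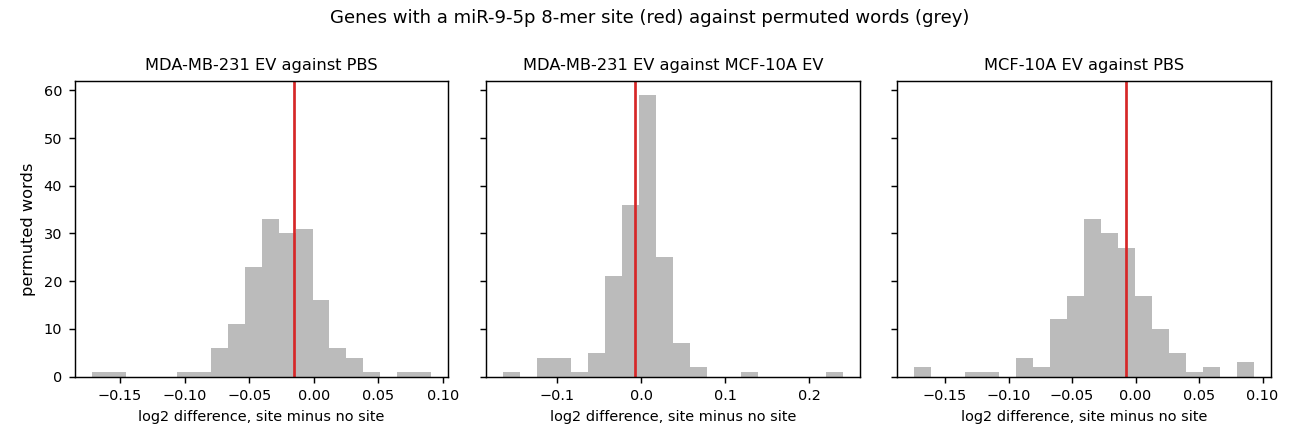
Difference in mean log2 change between genes with and without a word in the 3' UTR (horizontal axis, log2 units), as counts of permuted words (vertical axis) for each of the 3 comparisons; grey bars are words made of the same bases and the red line is the miR-9-5p 8-mer. The red line lies among the grey bars, at -0.015 in MDA-MB-231 EV against PBS.

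The comparison of MDA-MB-231 EV with MCF-10A EV sets cancer vesicles against those of non-tumorigenic cells. Gli1, the transcription factor target of hedgehog signalling, was at 0.0767 ± 0.0666 TPM (SD, n = 3) after MDA-MB-231 EVs and 14.8 ± 3.41 TPM after MCF-10A EVs, a log2 change of -3.86 ± 0.37 (limma adjusted p = 0.00113). Tmem254a, a membrane protein gene, was higher after MDA-MB-231 EVs (32.1 ± 13.2 against 2.18 ± 0.693 TPM; 3.31 ± 0.47, 0.0208). So were Tm4sf5, a tetraspanin relative (3.13 ± 0.51, 0.0427), and Il11ra2, a copy of the interleukin 11 receptor gene (3.11 ± 0.48, 0.0353). The histone gene H2bc21 (-3.17 ± 0.52, 0.0427) and Mup13, a major urinary protein (-4.14 ± 0.66, 0.0409), were lower. For each of these genes the PBS libraries lay on the side of MDA-MB-231 EV. PBS means were 0.153 TPM for Gli1, 44.2 for Tmem254a and 13.6 for Tm4sf5. In PBS 1 to 3 Il11ra2 was at 4.51, 12.2 and 9.65 TPM, H2bc21 at 1.12, 0.93 and 1.73, and Mup13 at 1.5, 0.17 and 0. The departure thus lies in the MCF-10A EV libraries, not in those after cancer vesicles. With the replicate number as a block, given below, Gli1 and Il11ra2 stayed called and Tmem254a, Tm4sf5, H2bc21 and Mup13 did not. Il11ra2, H2bc21 and Mup13 belong to families of near copies, and whether reads are shared between copies was not tested. Limma called 28 genes, 18 higher and 10 lower, among 492 at an unadjusted p under 0.05 with 643 expected by chance. The groups did not overlap for 840 genes (6.53%, chance 10%).

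Of these 28 genes, 17 were listed at 0 in every library of the MCF-10A EV group and above 0 in all 6 others, or the reverse. The cytochrome oxidase gene mt-Co2 was listed at 0 in all MCF-10A EV libraries and at 681, 271 and 341 TPM in MDA-MB-231 EV 1 to 3 (limma adjusted p = 1.6e-04). The ribosomal RNA gene Rn18s-rs5 was at 0 against 1814, 1163 and 3962 TPM. 7SK, the RNA that holds the elongation factor P-TEFb, was at 0 against 35.1, 23.7 and 198 TPM, and Spata5l1 at 0 against 4.13, 3.87 and 8.31 TPM. The signal recognition particle RNA genes Rn7s1 and Rn7s2 had identical values of 75.9, 135 and 397 TPM, so their reads cannot be assigned to either. In the other direction Cd28, the T cell costimulatory receptor, was listed at 0 in every PBS and MDA-MB-231 EV library and at 15.5, 43.2 and 51.0 TPM in MCF-10A EV 1 to 3. Only 3 of the 21 lymphocyte markers were kept by the filter, so the Cd28 values cannot be read as T cell expression. AI847159 was at 0 against 32.9, 33.2 and 25.4 TPM, and Gtsf2 at 0 against 16.8, 6.28 and 7.74 TPM. Snora73b was at 0 in all MDA-MB-231 EV libraries and at 22.9, 9.19 and 10.5 TPM in the MCF-10A EV libraries (limma adjusted p = 0.0286). Assembled loci were likewise at 0 in the MCF-10A EV libraries alone. This group and the way its libraries were quantified therefore cannot be told apart, and no value within one batch could be had. On features shared by both sets, with each library rescaled to the same total, 3 genes were called. This alternative was chosen after seeing the data, and its 2 changes were not tested apart.

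With the replicate number as a block over all 9 libraries, 15 genes were called, of which 14 were among the 28. Limma adjusted p with the block was 0.0906 for Tmem254a and Spata5l1, 0.160 for Tm4sf5, Mup13 and H2bc21, 0.110 for Snora73b and 0.0539 for Gtsf2, and the 12 called lists were the same. The other 7 calls lost with the block were of predicted genes and pseudogenes. The count was 46 with array weights, 17 with the filter at 5 TPM, and 11 both with no filter and with only the libraries of the groups compared. Single libraries moved this count and these calls too. The count was 15 without MCF-10A EV 2, 13 without MCF-10A EV 3 and 17 without MDA-MB-231 EV 2. Gli1 stayed called in each leave-out (limma adjusted p at most 0.0243), though not with the filter at 5 TPM, and so did mt-Co2, Rn18s-rs5, Rn7s1, Rn7s2, 7SK, Cd28 and AI847159. Without MCF-10A EV 3 limma adjusted p was 0.137 for Tmem254a, 0.253 for Tm4sf5, 0.170 for Il11ra2, 0.252 for Spata5l1, 0.256 for Mup13 and 0.0944 for Gtsf2. It was 0.273 for H2bc21 without MCF-10A EV 2 and 0.140 for Snora73b without MDA-MB-231 EV 1. Tmem254a stayed called in 4 of 9 leave-outs, Tm4sf5, Il11ra2 and Mup13 in 2, H2bc21 in 1 and Spata5l1 in 0.

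Among the groups, stellate cell and fibroblast markers were higher after MDA-MB-231 EVs than after MCF-10A EVs, with 17 of 18 above 0 and a median log2 change of 0.70 (camera adjusted p = 4.9e-04; with an estimated correlation the adjusted p was 0.618). At the preset correlation they stayed called in each leave-out (at most 0.0316), with a median of 0.41 without MDA-MB-231 EV 1. Rgs5, a marker of pericytes and stellate cells, was at 24.5 ± 4.84 against 7.70 ± 1.85 TPM (1.55 ± 0.36, limma adjusted p = 0.333 over all genes and 0.0233 over the list alone). Hgf gave 1.26 ± 0.47 and Colec11 1.11 ± 0.42. The other lists called upward had an adjusted p of 0.682 (fatty acid oxidation) or 0.618 (the rest) with an estimated correlation. Sinusoidal endothelial markers were called with them (median 0.68, 18 of 19 above 0, 0.00176; Tek 1.56 ± 0.63, Clec4g 1.02 ± 0.46). So were fatty acid oxidation and PPARA targets (0.60, 29 of 30, 1.6e-04). There the omega-hydroxylase Cyp4a10 gave 3.10 ± 0.80 and the trifunctional protein gene Hadha 1.72 ± 0.53. Xenobiotic metabolism (0.87, 19 of 24, 9.2e-04; Cyp2b10 2.40 ± 0.64), female-biased genes (0.95, 18 of 21, 0.00274; Cyp2b9 1.77 ± 0.68) and gluconeogenesis (0.51, 19 of 23, 0.0146; Pcx, pyruvate carboxylase, 1.44 ± 0.46) were also called upward. Medians moved to 1.01 for oxidation without MDA-MB-231 EV 3 and to 0.54 for xenobiotic metabolism without MDA-MB-231 EV 1.

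Acute phase proteins were lower after MDA-MB-231 EVs than after MCF-10A EVs (21 of 25 below 0, median -0.71, camera adjusted p = 2.2e-07; Orm2 -2.94 ± 0.94, Saa1 -3.29 ± 1.69). With an estimated correlation the adjusted p was 0.618 for them and for the other lists called downward, save NF-kB cytokines (0.753). Also lower were neutrophil markers (16 of 19, -1.09, 2.2e-07; Mpo -2.55 ± 1.24, Camp -2.91 ± 1.47). Monocyte markers (-0.64, 12 of 13, 3.0e-04; Spp1 -1.18 ± 0.62), interferon response (-0.26, 19 of 26, 4.9e-04; Oas1a -1.04 ± 0.40), heat shock (-0.37, 10 of 14, 0.00176; Hsp90aa1 -1.42 ± 0.54) and NF-kB cytokines (-0.26, 12 of 16, 0.00923) were also called downward. MCF-10A EV 1 carried much of the inflammatory part. Without it medians were -0.04 for acute phase (camera adjusted p = 0.214), 0.30 for neutrophil (0.707), 0.12 for monocyte (0.386) and 0.61 for NF-kB genes (0.424), which turned up. Female-biased genes had 0.28 (0.934). Other calls were lost with medians nearer to those of all libraries: 0.51 for oxidation and 0.66 for xenobiotic metabolism (both 0.301), 0.48 for gluconeogenesis (0.130) and 0.60 for endothelial markers (0.320). Without MDA-MB-231 EV 1 they were 0.30 for oxidation and 0.32 for endothelial markers (both 0.0818) and -0.27 for NF-kB (0.114). Without MDA-MB-231 EV 2 they were 0.54 for oxidation (0.133), 0.67 for gluconeogenesis (0.0646), -0.02 for NF-kB (0.0639) and 0.62 for female-biased genes (0.471). Without MDA-MB-231 EV 3 they were 0.24 for gluconeogenesis (0.0773), -0.07 for interferon (0.124) and 0.01 for heat shock (0.935). Where calls were kept, the median without MCF-10A EV 2 was -1.17 for acute phase, -2.42 for neutrophil, -1.18 for monocyte, -0.72 for NF-kB and -0.48 for interferon genes. Without MCF-10A EV 3 it was -1.66 for neutrophil and -0.47 for NF-kB genes, and without MDA-MB-231 EV 3 -1.71 and -0.80. For interferon it was -0.49 without MDA-MB-231 EV 1 and -0.02 without MDA-MB-231 EV 2, and for heat shock -0.73 without MDA-MB-231 EV 2. With array weights 2 lists were called.

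None of the sterol lists was called between the vesicle groups, which does not show that they were alike. In the simulation of this comparison 2% of genes with a log2 change of 1 were recovered, and 26% at 2. Cholesterol synthesis had 12 of 23 genes above 0 and a median of 0.09, below that of all genes by camera's direction (camera adjusted p = 0.470). SREBP processing had 7 of 14 and 0.06 (0.752), also with a downward test against a median above 0. Cholesterol export and LXR targets had a median of 0.34 (0.0951) and bile acid genes 0.48 (0.0800). Insig1 gave -0.04 ± 0.67, Insig2 0.44 ± 0.50, Scap 0.45 ± 0.36, Srebf1 -0.19 ± 0.62 and Srebf2 0.41 ± 0.39. Hmgcs1 gave -0.84 ± 0.65, Sqle -0.14 ± 0.55, Cyp7a1 -0.08 ± 0.66 and Abca1 0.16 ± 0.53, with a limma adjusted p of 1 for each. Abcb4 gave 1.68 ± 0.53 (0.857). Cholesterol synthesis was called downward without MCF-10A EV 3 (median -0.15, 0.0307) and without MDA-MB-231 EV 1 (-0.35, 0.0286). Bile acid genes were called upward without MCF-10A EV 2 (0.0224), MCF-10A EV 3 (0.0410) or MDA-MB-231 EV 3 (0.0037), and LXR targets upward without MDA-MB-231 EV 3 (0.0145) or both libraries that stand apart (0.0122). Camera's direction was downward against a median above 0 for cholangiocyte markers (0.02), ribosomal proteins (0.08), male-biased genes (0.04), immediate early genes (0.06) and pericentral genes (0.29). The same held for nuclear oxidative phosphorylation genes (0.16), the unfolded protein response (0.27) and matrix (0.04). Fat markers had a median of -0.04 and a mean of 0.09.

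Set against PBS, MCF-10A EVs address what vesicles of non-tumorigenic cells do by themselves. Acute phase proteins, the liver's inflammatory secretion, were called upward, with 25 of 25 above 0, none past the threshold by itself, and a median log2 change of 1.21 (camera adjusted p = 3.6e-11; with an estimated correlation the adjusted p was 0.836, as for every list called in this comparison). The size rests on MCF-10A EV 1: the list's mean relative to the 9 libraries and all tested genes was 2.51 there and -0.31 and 0.39 in MCF-10A EV 2 and 3, and without MCF-10A EV 1 the median was 0.37. Saa1 gave 4.02 ± 1.69, Saa2 4.40 ± 1.93, Orm2 2.69 ± 0.94 and Orm1 1.62 ± 0.62. Neutrophil markers were called upward too (17 of 19 above 0, median 2.01, 5.7e-08; S100a8 3.79 ± 1.58, Camp 3.52 ± 1.47), as were NF-kB cytokines (15 of 16, 0.66, 2.6e-04; Cxcl1 1.77 ± 0.74, Ccl2 1.40 ± 0.79). Also called upward were monocyte markers (12 of 13, 0.59, 0.0208; Chil3 2.50 ± 1.40), ribosomal proteins (26 of 27, 0.39, 2.6e-04; Rps23 0.87 ± 0.48), cell cycle genes (12 of 14, 0.56, 0.0264; Top2a 1.05 ± 0.64) and NRF2 targets (13 of 13, 0.38, 0.0268; G6pdx 1.20 ± 0.49). Mitochondrially encoded genes were lower (13 of 13 below 0, median -1.03, 6.9e-12; mt-Cytb -1.42 ± 0.51). Of them mt-Co2 is listed at 0 in each MCF-10A EV library, which is no measured change. On features shared by both sets, with libraries rescaled, an alternative chosen after seeing the data, the other 12 had a median of -1.01 (6.2e-09), and without PBS 1 the 13 had one of -0.67. Stellate markers (17 of 18 below 0, -0.41, 1.3e-05) and sinusoidal endothelial markers (17 of 19, -0.45, 0.00117; Clec4g -0.80 ± 0.46) were called downward, with no member past the threshold over all genes. Rgs5 was at 7.70 ± 1.85 against 30.3 ± 5.53 TPM (-1.85 ± 0.36, limma adjusted p = 0.112 over all genes and 0.00635 over the list alone), and Colec11 gave -0.74 ± 0.42. MCF-10A EV 1 alone held 2692 TPM of S100a9, 284 of Camp and 117 of Mpo. Without it medians were 0.36 for neutrophil markers (camera adjusted p = 0.108), -0.09 for NF-kB (0.932), -0.05 for monocytes (0.849), -0.04 for the cell cycle (0.993) and -0.28 for endothelial markers (0.170). Acute phase proteins stayed called in each leave-out (at most 1.6e-04), as did stellate markers (at most 0.0138) and mitochondrial genes. Ribosomal proteins (0.06, 0.852) and monocyte markers (0.05, 0.818) lost the call without PBS 1, endothelial markers without PBS 2 (-0.22, 0.195) and the cell cycle without PBS 3 (0.39, 0.128). Where calls were kept, medians were 1.12 for NF-kB and 3.21 for neutrophil genes without MCF-10A EV 2, 1.16 for monocyte markers and 0.71 for ribosomal proteins without PBS 2, and -0.69 for endothelial markers without PBS 3. Array weights left 4 lists called. NRF2 targets lost the call without PBS 1 (0.08, 0.535), MCF-10A EV 1 (0.19, 0.0761) or MCF-10A EV 2 (0.27, 0.149).

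Cholesterol synthesis and uptake were called upward after MCF-10A EVs, with 20 of 23 genes above 0 and a median of 0.37 (camera adjusted p = 0.0264; with an estimated correlation the adjusted p was 0.836). Fdft1, squalene synthase, gave 1.08 ± 0.59 and Dhcr7, the last reductase of the pathway, 0.61 ± 0.48. The call was lost without PBS 1 (median 0.13, 0.535), PBS 2 (0.28, 0.187), MCF-10A EV 1 (0.17, 0.170) or MCF-10A EV 2 (0.149), though there the median was 0.41. Array weights turned it down (0.0550). Without PBS 3 the median was 0.64. SREBP processing had a median of 0.35 (11 of 14 above 0, 0.0640) and was called without PBS 3 (median 0.45, 0.0149), MCF-10A EV 3 (0.51, 0.0217) or MDA-MB-231 EV 1 (0.35, 0.0340). On features shared by both sets, with libraries rescaled, an alternative chosen after seeing the data, 16 lists were called. Beside the 11 these were SREBP processing upward (0.36, 0.0419) and, downward, fatty acid oxidation (-0.02, 0.0369) and the matrix, male-biased and fat lists (0.0402 each). In that list Mbtps1, the site-1 protease that cleaves SREBP, was at 39.5 ± 3.34 against 9.85 ± 2.36 TPM (1.92 ± 0.43, limma adjusted p = 0.248 over all genes and 0.0165 over the list alone). It gave -1.33 ± 0.43 in MDA-MB-231 EV against MCF-10A EV (0.924). The other sterol genes gave 0.23 ± 0.67 for Insig1, 0.57 ± 0.50 for Insig2, 0.34 ± 0.62 for Srebf1, -0.21 ± 0.39 for Srebf2 and 0.34 ± 0.36 for Scap. They were -0.14 ± 0.65 for Hmgcs1, 0.32 ± 0.55 for Sqle, 0.03 ± 0.66 for Cyp7a1 and 0.07 ± 0.53 for Abca1, each with a limma adjusted p of 1. Fatty acid oxidation had a median of -0.04 (0.0711; Cyp4a10 -2.92 ± 0.80) and was called downward without PBS 1 (median -0.32, 2.0e-05), MCF-10A EV 2 (-0.18, 0.00112) or MCF-10A EV 3 (-0.07, 0.0395). LXR targets had a median of 0.07 (0.921), above 0 where camera's direction was downward. Cholangiocyte markers had a median of 0.01 and a downward test. The circadian clock, the glucocorticoid response and periportal genes had medians of 0.02, 0.03 and 0.04 over means of -0.01, -0.01 and -0.02.

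At the level of single genes limma called 25 in MCF-10A EV against PBS, 7 higher and 18 lower, among 411 at an unadjusted p under 0.05 with 643 expected by chance. The groups did not overlap for 989 genes (7.69%, chance 10%). Of the 25, 16 were listed at 0 in the whole MCF-10A EV group or in all 6 other libraries. Among the others, Gli1 was higher (14.8 ± 3.41 against 0.153 ± 0.0473 TPM; 3.76 ± 0.37, limma adjusted p = 0.00138). Lower were Chn1, a Rac GTPase-activating protein (-6.41 ± 0.98, 0.0309), Tmem254a (-3.75 ± 0.47, 0.00818), Tm4sf5 (-3.73 ± 0.51, 0.0138) and Apba2 (-3.18 ± 0.50, 0.0358). Chn1, Tm4sf5 and Apba2 were near 0 after MCF-10A EVs, with means of 0.0833, 0.02 and 0.0367 TPM. After PBS their means were 103, 13.6 and 9.91 TPM. For Chn1 and Tm4sf5 too, the group and its quantification cannot be told apart. Apba2 was also low after MDA-MB-231 EVs, at 0.74, 0.78 and 0.60 TPM in MDA-MB-231 EV 1 to 3, without passing the threshold there. Its low values are thus not confined to the MCF-10A EV libraries, though quantification may still enter its change here. The genes at 0 included the ones named above. In PBS 1 to 3 mt-Co2 was at 401, 202 and 69.1 TPM, Rn18s-rs5 at 893, 2153 and 3130, 7SK at 111, 41.1 and 53.6, Rn7s1 and Rn7s2 at 66.7, 220 and 316, and Spata5l1 at 7.08, 3.47 and 7.08, against 0 in each MCF-10A EV library. Cd28, AI847159 and Gtsf2 were at 0 in PBS. The count was 54 without PBS 1, 15 without PBS 3, 14 without MCF-10A EV 3 and 59 without MDA-MB-231 EV 3. Array weights gave 548, of which 179 were higher, only the libraries of the groups compared 48 (11 higher), a pseudocount of 0.1 gave 40 (6 higher), no filter 12 and quantile normalization 30 (12 higher). Without 1 library limma adjusted p reached 0.163 for Chn1 (MCF-10A EV 1), 0.192 for Apba2 and 0.0679 for Tmem254a (MCF-10A EV 3). It reached 0.0885 for Gtsf2 (MCF-10A EV 3), and 0.0948 for Tm4sf5 and 0.243 for Spata5l1 (PBS 3). On features shared by both sets, with libraries rescaled to the same total, 7 genes were called, and with PBS 1 and MDA-MB-231 EV 3 both left out 85. Both alternatives were chosen after seeing the data.

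The log2 changes of both vesicle groups against PBS correlated across the 12860 genes with Pearson's r = 0.469, where genes are not independent replicates. Simulated unchanged groups that share simulated PBS libraries, with genes drawn independently, gave 0.50 ± 0.011 (SD of 100 simulations). The SDs of this simulation leave out the correlation between genes, so they cannot show how far the observed values lie from it. The covariance was 0.194 against 0.230 ± 0.008, a difference of -0.036, and 66.7% of genes had the same sign against a simulated 66.6%. The 3 PBS libraries are too few to split so that each part keeps a pair. Without MCF-10A EV 1 the correlation was 0.261, without MDA-MB-231 EV 2 0.306 and without PBS 2 0.611. Unchanged groups were simulated for all 9 libraries only, so these correlations have no such value to be read against.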

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

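The fit without PBS 1 and MDA-MB-231 EV 3, the fit on features shared by both sets of libraries and the test of the assembled loci were chosen after the results were seen. The other alternatives were planned. Wherever shared features are given, the libraries were also rescaled to the same total, so the 2 changes cannot be told apart. For MDA-MB-231 EV against PBS the count of genes stayed at 0 under each scaling, pseudocount, filter, weighting and block and with the assembled loci, was 0 to 24 with a library left out, and 28 without the libraries that stand apart. Against MCF-10A EV, the 28 genes became 11 with no filter, 17 with the filter at 5 TPM, 11 with only the groups compared, 46 with array weights, 15 with the replicate number as a block, 3 on shared features and 13 to 31 with a library left out. For MCF-10A EV against PBS, the 25 genes became 40 with a pseudocount of 0.1, 12 with no filter, 48 with only the groups compared, 548 with array weights, 7 on shared features, 85 without the libraries that stand apart and 14 to 59 with a library left out. The 13 lists of MDA-MB-231 EV against PBS became 4 with quantile normalization, 7 with the filter at 5 TPM, 4 with array weights, 7 without the libraries that stand apart and 4 to 17 with a library left out. Array weights left 2 of the 12 lists against MCF-10A EV (7 to 16 with a library left out) and 4 of the 11 of MCF-10A EV against PBS (7 to 17). An estimated correlation gave 0 lists in each comparison and fry gave 0. The difference of genes with a miR-9-5p site ranged from -0.047 to 0.0063 over leave-outs in MDA-MB-231 EV against PBS. Against MCF-10A EV it was 0 with the 10 most abundant genes removed, 0.0028 with a pseudocount of 0.1, 0.015 with the 7-mer and -0.041 to 0.018 over leave-outs. In MCF-10A EV against PBS it was 0.010 with the filter at 5 TPM, 0.026 with array weights, 0.0029 on shared features, 0.010 without the libraries that stand apart and -0.031 to 0.023 over leave-outs. The correlation of both vesicle comparisons ranged from 0.261 to 0.611 over leave-outs. Lists turned direction, with camera adjusted p of 0.756 for matrix with the filter at 5 TPM in MDA-MB-231 EV against PBS. In that comparison leave-outs ranged from 2.4e-09 to 0.617 for heat shock (highest without MDA-MB-231 EV 3), 1.6e-04 to 0.956 for matrix (PBS 2), 2.4e-09 to 0.787 for male-biased genes (MDA-MB-231 EV 3) and 9.2e-08 to 0.699 for ribosomal proteins (PBS 1), each turned at the highest. Against MCF-10A EV they were 2.3e-06 to 0.424 (NF-kB, highest and turned without MCF-10A EV 1) and 0.990 (heat shock, without the libraries that stand apart), and in MCF-10A EV against PBS 0.0550 (cholesterol synthesis) and 0.848 (sinusoidal endothelium), both with array weights. For none of the changes above, save those of the filters and the fewer libraries fitted, is the reason shown by a value, and the cause was not tested. Of the named genes' alternatives, 1829 of 1850, 1751 of 1883 and 1709 of 1787 kept direction and side of the threshold in the same order of comparisons; 0, 106 and 47 lost a call, 8 gained one, and 21, 26 and 23 changed the sign of a value not called. Libraries of the same number correlated from -0.389 to 0.5 for MDA-MB-231 EV and PBS (other pairs -0.595 to 0.625) and from -0.206 to -0.09 for MCF-10A EV and PBS (-0.336 to 0.355), where 2 and 0 of 6 samples correlated best with their own number, against 5 of 6 between the vesicle groups. Against PBS the block kept 11 of the 13 MDA-MB-231 EV lists, not gluconeogenesis (0.0594) or xenobiotic metabolism (0.0503), and gave 20 MCF-10A EV genes, 17 of them among the 25, with Chn1 at 0.126, Apba2 at 0.0938 and Tm4sf5 and Spata5l1 at 0.0637; that no pairing is shown there leaves the reason open. Between the vesicle groups it changed no list call, and no call of a named gene beyond those given. Shared features with rescaled libraries gave 12, 12 and 16 lists in the same order of comparisons, against 13, 12 and 11. Leave-outs leave an arm of 2 libraries. The count-based tool was not run, since the table holds no counts, and without counts no limit set by depth can be given.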

Other observations

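The genes of these first paragraphs, save Scd1, were chosen after their values were seen, and none passed the threshold. Usp2, a rhythmic deubiquitinase, was at 33.0 ± 25.6 TPM (SD, n = 3) after MDA-MB-231 EVs, 12.2 ± 2.13 after PBS and 15.3 ± 5.72 after MCF-10A EVs. Ahr, the receptor for aromatic pollutants, was at 5.11 ± 1.48 TPM after MCF-10A EVs and 12.7 ± 2.75 after PBS, a log2 change of -1.18 ± 0.40, and its target Cyp1a2 at 240 ± 128 and 502 ± 204 TPM. Limma adjusted p over all genes was 0.893 for Ahr and 1 for the others.

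Kupffer markers were not called in MCF-10A EV against PBS (median log2 change 0.44, camera adjusted p = 0.275), though they were called upward without PBS 2 (0.00903) or MCF-10A EV 2 (0.0484). Marco, a scavenger receptor, was at 298 ± 438 TPM against 28.7 ± 15.5 after PBS, and Clec4f, a Kupffer cell lectin, at 69.0 ± 59.6 against 162 ± 41.4 TPM, both with a limma adjusted p of 1. The SD of Marco after MCF-10A EVs exceeds its mean, so a single library carries most of that value. Scd1, the desaturase that makes oleate, was at 705 ± 125 against 328 ± 74.3 TPM (log2 change 1.11 ± 0.44, limma adjusted p = 1). Col6a1, a chain of microfibrillar collagen, was at 1.39 ± 0.208 against 5.75 ± 1.57 TPM (-1.48 ± 0.47, limma adjusted p = 0.763).

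The tests of unspliced nuclear RNA, of a lower share of hepatocyte RNA and of a separate quantification were chosen or changed after the results were seen; those of genomic DNA and of the other splits were planned before their result. The 6 libraries of a comparison make 10 splits of 3 against 3, too few for a share under 0.05. For MDA-MB-231 EV against PBS the real split called 0 genes and the highest of the others 2, so that all 10 gave as many. For MDA-MB-231 EV against MCF-10A EV the real split called 28 and the highest other 1, and for MCF-10A EV against PBS 25 and 1, so that 1 of the 10 splits gave as many in each. The 3 other splits of MDA-MB-231 EV against MCF-10A EV that part as many same-numbered pairs as the real one called 0.

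PBS 1 and MDA-MB-231 EV 3 stand apart from their groups in the same direction, and their deviations correlate across genes with Pearson's r = 0.625, where genes are not independent replicates. Secreted hepatocyte proteins had medians of -1.23 and -1.45 log2 units against the other two libraries of the group, and mitochondrially encoded genes 1.43 and 1.18. The number of olfactory and vomeronasal receptor genes above 0 was at most 182 in these libraries and up to 198 in the other 7. It was lowest in MDA-MB-231 EV 2, at 96. The higher number predicted for genomic DNA was thus not seen. Such a number depends on depth, which is unknown, so it cannot decide on genomic DNA. Assembled loci held 3.015% and 5.697% of TPM in these libraries and at most 2.227% in the other PBS and MDA-MB-231 EV libraries. Kupffer markers, with medians of -0.778 ± 0.147 and -0.664 ± 0.271 (SE), fell where a lower share of hepatocyte RNA would raise them. This bound on the Kupffer markers was set after the values were seen; sinusoidal endothelial (0.191 ± 0.236 and -0.033 ± 0.360), stellate (-0.052 ± 0.167 and -0.066 ± 0.280) and cholangiocyte markers (-0.215 ± 0.455 and 0.249 ± 0.556) stayed within their spread, so the bound on these lists written earlier was not met. Unspliced nuclear RNA stays open. Deviation rose with genomic span with a Spearman rho across genes of 0.25 and 0.113, past the value of 0.1 set beforehand. MDA-MB-231 EV 1, which is outside the pattern, gave 0.129, and MDA-MB-231 EV 2 gave -0.29. Each deviation is taken from the other libraries of the group, so the values within a group are tied. A low MDA-MB-231 EV 2 raises both others, so neither 0.113 nor 0.129 can decide. The nuclear RNAs, chosen after the values were seen, did not all rise. Neat1 was at 148 and 227 TPM against at most 90.3 TPM in the others, Xist at 320 and 273 against at most 74.9 TPM, and Kcnq1ot1, near the floor, at 0.19 and 0.18 against at most 0.06 TPM. Malat1 was at 57.3 and 54.0 TPM, within the 5.66 to 81.9 TPM of the others. No biological explanation was tested, since no group of the design holds these libraries together.

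Of the 23 genes called in both comparisons with MCF-10A EV and in the same direction there, 16 were listed at 0 throughout that group or throughout the other 6 libraries. That is 69.6%, against 0.412% of all tested genes. A gene at 0 throughout a group has no spread there, which favours a call, so part of this excess is built in. Without any test of groups, 20 Ensembl features with a mean of at least 10 TPM in the other libraries were at 0 in MCF-10A EV only. For 83 other choices of 3 libraries this number was at most 2. Assembled loci are at 0 in the MCF-10A EV libraries as well. A separate quantification of the MCF-10A EV libraries, with another annotation or other settings, may explain those 16 genes. The remaining 7 are above 0 in a library of each set, but most are near 0 in one: Tm4sf5, Gm47076, Gm14026 and Tuba5-ps, of which the last 3 were chosen after their values were seen, were at most at 0.16 TPM in MCF-10A EV, and Gli1 at most at 0.19 TPM in the other 6 libraries. For all 23 the group and its quantification cannot be told apart. The 16 genes at 0 throughout a set, like the assembled loci, show no measured change and are no evidence of an effect of the vesicles. For the remaining 7 such an effect, which the design names, stays open and untested.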
